A study of Homo sapiens with 16 samples.

How the data were processed

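Messenger RNA of HCT116 cells was measured by sequencing in 16 libraries. Per the labels, mRNA was purified from isolated total RNA on beads, reverse transcribed and made into Illumina libraries. The values used are FPKM as deposited by the authors, with no further scaling in the main analysis. Per the submitters' processing notes edgeR was used and the genome was hg38 (GRCh38), with the edgeR version not given. The aligner, the program that assigned reads to genes and the gene annotation are not given in the sources used here. The column of each library was matched by its name to the sample title, and all 16 columns were used.

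The table holds 20271 genes by Ensembl identifier. Symbols were taken from the table, except that 28 symbols turned into dates and 210 blank ones were filled from GENCODE release 29, and 99.6% of the genes then had a symbol of that release. Gene positions are those of the same release on GRCh38. No raw counts were at hand, so relative depth was read from the low values. Genes under 1 FPKM take values in steps that shrink with depth, and the most frequent ratio of such values between libraries, in log2 windows of 0.01, was used as their depth ratio. The ratio of replicate 2 to replicate 1 was 4.26 to 4.88 in the 5 close pairs and 4.89 to 6.51 in the 3 others.

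The spread of each replicate pair beyond counting error was estimated from genes with a mean of at least 5 FPKM. The squared log ratio was regressed on the counting variance, which depends on level, median transcript length and depth, over 30 bins, and the root of the intercept is the extra spread. The estimate was tested on simulated data: pairs with a true extra spread of 0, 2, 5, 10 and 20% gave -0.652, 1.73, 5.12, 10.2 and 18.3%. At 100 FPKM and above the median absolute log2 difference between replicates was 0.0518 to 0.0668 in the close pairs and 0.176 to 0.249 in the others.

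Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and an intensity trend. Genes with a mean of at least 1 FPKM over all libraries were kept, 10662 in number. One fit of 8 group means left 8 residual degrees of freedom, with 3.15 prior degrees of freedom. An adjusted p under 0.05 by the Benjamini-Hochberg method within each comparison was the threshold, and a 2-fold change was counted apart. For list counts the adjustment was also made over the list alone. With 2 libraries per group the smallest exact p of a 2 against 2 test is 0.333, so exact tests were not used. Interactions were tested as differences of differences in the same fit.

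There were 17 gene lists, written from textbook knowledge, and 15 of them were tested with camera in limma at a preset correlation of 0.01 between genes, with adjustment over 180 tests of 15 lists in 12 comparisons. Of these 86 passed, and 0 passed when the correlation was estimated from the 8 residual degrees of freedom, where the lowest adjusted p was 0.262. That correlation was estimated over the replicate pairs of all groups. The pairs with the larger spread thus enter it also in comparisons that use none of their libraries. The lists were p53 pathway regulators, p53 activated targets, p53 targets in growth arrest, apoptosis, DNA repair and metabolism, G2/M and mitosis, DNA replication and G1/S, NF-kB targets, type I interferon response, NRF2 targets, epithelial junctions and keratins, ATF4 and ER stress, cholesterol synthesis and reference genes. Marker genes of other cell types and mitochondrially encoded genes were read for level only. p53 depletion in iASPP-depleted cells and the p53 by iASPP interaction in each nutlin state lie outside the 180 tests, and their list tests were adjusted over the 15 lists of each.

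Genes were named by a fixed rule. Each comparison gives PPP1R13L, MDM2 and CDKN1A, then the 8 largest rises and 8 largest falls past the threshold whose libraries did not overlap, leaving out genes without a symbol or with clone names. From each list that passed, the 4 members past the threshold with the largest change were taken, and from each other list the 2 with the smallest p. A gene named in 1 comparison could be named in others, and 218 genes were named in all. Some genes that the rule picks are not reported here. The report prints examples from the rest.

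The whole procedure was tested on simulated data with 50 genes changed at each size. Noise was normal, independent and equally wide for a gene in all libraries, and only genes with a mean log2(FPKM + 1) above 3 were changed. The unequal spread of the replicate pairs was not simulated, so the shares below need not hold for these data or for genes of lower level. For the nutlin comparison, with 10547 genes run, 14, 62, 96 and 100% were recovered at log2 changes of 0.5, 1, 2 and 3, with 6 false calls among 10347 unchanged genes. For the nutlin by iASPP interaction, with 10563 genes run, the shares were 2, 34, 92 and 98%, with 10 false calls among 10363. For the p53 by iASPP interaction, with 10549 genes run, they were 14, 70, 96 and 98%, with 9 false calls among 10349.

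Alternatives chosen in advance were a pseudocount of 0.1, no filter beyond a mean above 0 (17696 genes), median-of-ratios scaling, the replicate number as a block, each library left out in turn, and the estimated correlation. Chosen after the data were seen were the omission of the 3 diverging libraries (13 libraries left), close pairs counted once (11 samples with 3 residual degrees of freedom) and the interactions split by nutlin state. A count model was not run because no counts were used here. Shared calls were compared with n1 x n2 / N, and for the pair with shared controls with 100 simulated draws. Genes with a mean below the level filter were left out of the tests because their log values mostly rest on few reads. Some of them, such as HBB and CD79A, lay above that level in at least 1 library. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.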

Results

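The HCT116 colon cancer line, labelled as wild type for p53, had p53, iASPP or both silenced by siRNA for 3 days. Nutlin was then added to some of the groups for 0.5 days more. The 8 groups were CTR siRNA, p53 siRNA, iASPP siRNA and p53+iASPP siRNA, each without and with nutlin, with 2 libraries per group and 16 in all. The labels give no statement that the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The deposited table lists FPKM for 20271 genes, of which 17696 were above 0 in some library and 10662 had a mean of at least 1 FPKM and were tested. Each library had between 10068 and 10726 genes at 1 FPKM or above. Relative sequencing depth, read from the step size of the low values, was 0.823 to 1.33 in replicate 1 and 3.67 to 7.68 in replicate 2.

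In 5 groups, namely the 4 without nutlin and CTR siRNA+nutlin, the replicates differed by only 2.31 to 4.14% beyond counting error, where pairs simulated with counting error alone gave -0.652%. Pairs simulated with a true extra spread of 2 and 5% gave 1.73 and 5.12%, so the observed values lie above counting error alone in this model. These pairs may still be the same library sequenced again or cultures handled alike, and p-values that rest on them may measure technical spread. In the nutlin groups with p53, iASPP or both siRNAs the extra spread was 17.4, 24.3 and 18.0%, and their replicate 2 libraries are called the 3 diverging libraries below. The main fit used the same spread of a gene for all groups. Its standard errors and p-values are therefore likely too small for comparisons that use the 3 diverging libraries, and too large for the others if the close pairs show the true spread. Counts without these 3 libraries, and counts with each close pair averaged into 1 sample, are given beside the main counts. Both were added after the data were examined. Without the 3 libraries the spread was estimated from the 5 close pairs alone, and with close pairs averaged from the 3 diverging pairs alone. Larger counts in the former setting and smaller counts in the latter are therefore in part built in. The 12 planned comparisons, their thresholds, the 17 gene lists used for them and the rule for naming genes were fixed before the data were examined.

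**Figure D1:**
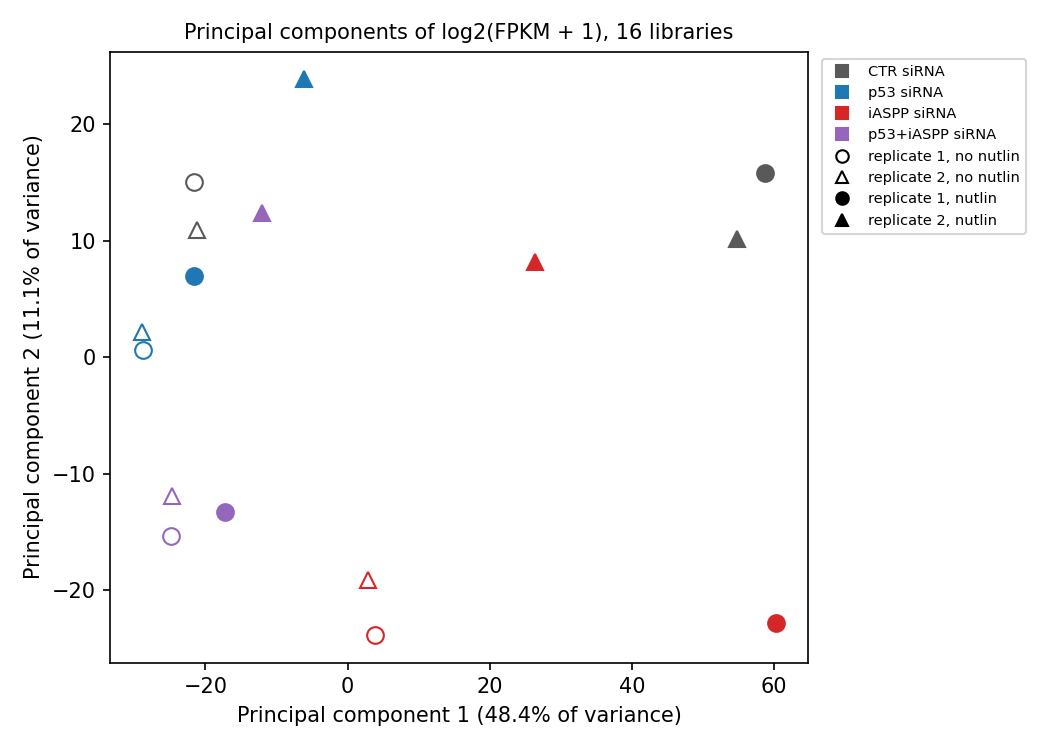
The 16 libraries on the first 2 principal components, which held 48.4% and 11.1% of the variance; circles are replicate 1, triangles replicate 2, and filled symbols had nutlin.

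The target of the iASPP siRNA was read first. PPP1R13L (ENSG00000104881, GRCh38 chromosome 19 from 45379634 to 45406349, minus strand), which encodes iASPP, stood at 9.32 ± 0.888 FPKM with CTR siRNA (mean ± SD, n = 2; libraries 9.95 and 8.69), 9.12 ± 3.16 with p53 siRNA (6.88 and 11.4), 0.410 ± 0.186 with iASPP siRNA (0.541 and 0.279) and 1.38 ± 0.490 with both (1.73 and 1.03). With nutlin the PPP1R13L values were 18.0 ± 1.25 FPKM (17.1 and 18.9), 15.9 ± 1.37 (16.8 and 14.9), 1.05 ± 0.346 (0.807 and 1.30) and 1.41 ± 1.46 (0.378 and 2.45) in the same order. PPP1R13L with iASPP siRNA was 4.40% of control without nutlin and 5.85% with it, and 14.8% and 7.86% with both siRNAs.

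PPP1R13L was lower with iASPP siRNA in each background: untreated (log2 change -2.88 ± 0.36, adjusted p = 0.00296), with nutlin (log2 change -3.22 ± 0.36, adjusted p = 0.00914), p53-depleted (log2 change -2.07 ± 0.36, adjusted p = 0.0307) and p53-depleted with nutlin (log2 change -2.95 ± 0.36, adjusted p = 0.0486). With close pairs counted once none of these calls was kept (lowest adjusted p = 0.962). The last was also lost with a pseudocount of 0.1 (adjusted p = 0.320), with no filter beyond a mean above 0 (0.179) and with the replicate block (0.0821). The p53-depleted call was lost with the same pseudocount (0.0720) and with no filter (0.0621), and some calls were lost with 1 library left out. All changes are limma differences of log2(FPKM + 1), given ± their standard error, which are smaller than FPKM ratios for genes of low level. Cells that had p53 siRNA are called p53-depleted below after the treatment.

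**Figure D2:**
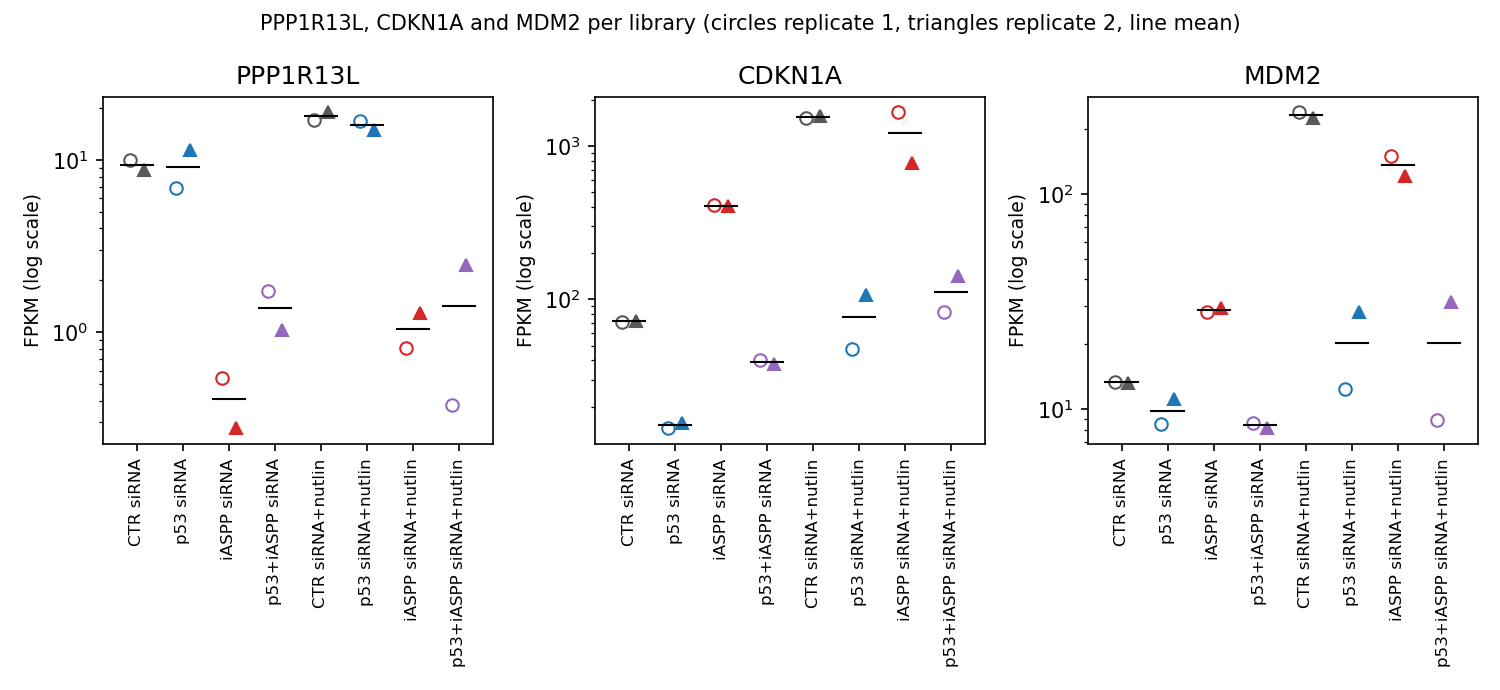
FPKM of PPP1R13L, CDKN1A and MDM2 in each library on a log axis; CDKN1A had a mean of 71.7 FPKM with CTR siRNA and 1543 FPKM with CTR siRNA+nutlin.

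The first comparison asked what nutlin, which blocks the binding of MDM2 to p53, did in cells with CTR siRNA. CDKN1A (ENSG00000124762, GRCh38 chromosome 6 from 36676460 to 36687339, plus strand), whose product p21 inhibits cyclin-dependent kinases, rose from 71.7 ± 1.42 FPKM to 1543 ± 47.7 FPKM (n = 2, log2 change 4.41 ± 0.38, adjusted p = 2.4e-05). MDM2 (ENSG00000135679, GRCh38 chromosome 12 from 68808176 to 68850686, plus strand), which encodes the E3 ligase for p53, rose from 13.3 ± 0.0845 FPKM to 232 ± 10.2 FPKM (log2 change 4.02 ± 0.45, adjusted p = 1.0e-04). TP53I3 (ENSG00000115129, GRCh38 chromosome 2 from 24077433 to 24085861, minus strand), a quinone oxidoreductase gene, rose from 7.60 ± 1.19 FPKM to 265 ± 29.9 FPKM (log2 change 4.95 ± 0.39, adjusted p = 1.5e-05). The stress cytokine gene GDF15 (ENSG00000130513) rose from 236 ± 0.0635 FPKM to 2494 ± 75.8 FPKM (log2 change 3.39 ± 0.24, adjusted p = 9.7e-06). Of the 95 measured p53 activated targets 77 rose and 1 fell (84 up and 1 down when adjusted over the list alone). Their median log2 difference was 1.25 (camera adjusted p = 2.8e-48, adjusted p = 0.262 with an estimated correlation). The shorter p53 lists share members with it. In growth arrest 13 of 17 rose, BTG2 by 2.41 and SFN by 2.39 (camera adjusted p = 1.4e-16, adjusted p = 0.268 with an estimated correlation). In apoptosis 16 of 21 rose and 1 fell, with FAS at 2.12 (camera adjusted p = 1.2e-14, adjusted p = 0.262 with an estimated correlation). In metabolism 17 of 20 rose, FDXR by 2.64 (camera adjusted p = 2.0e-18, adjusted p = 0.262 with an estimated correlation). In DNA repair 5 of 10 rose and 2 fell, with RRM2B at 1.73 (camera adjusted p = 0.0288, adjusted p = 0.526 with an estimated correlation). Adjusted over each list alone, the counts were 14 up, 17 up and 1 down, 19 up and 6 up and 3 down in that order.

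Genes of the cell division cycle fell with nutlin. AURKB (ENSG00000178999, GRCh38 chromosome 17 from 8204733 to 8210600, minus strand), a mitotic kinase gene, fell from 109 ± 9.19 FPKM to 2.89 ± 1.31 FPKM (n = 2, log2 change -4.86 ± 0.27, adjusted p = 3.8e-06). RRM2 (ENSG00000171848, GRCh38 chromosome 2 from 10120698 to 10131419, plus strand), a ribonucleotide reductase subunit gene, fell from 66.9 ± 0.0478 FPKM to 1.66 ± 0.392 FPKM (log2 change -4.68 ± 0.43, adjusted p = 3.1e-05). CDC6 (ENSG00000094804, GRCh38 chromosome 17 from 40287633 to 40304657, plus strand), needed to license replication origins, fell from 30.8 ± 0.359 FPKM to 1.03 ± 0.193 FPKM (log2 change -3.97 ± 0.30, adjusted p = 1.2e-05). All 35 genes of the G2/M and mitosis list fell, the same number when adjusted over the list alone, with a median of -3.68 (camera adjusted p = 1.4e-26, adjusted p = 0.268 with an estimated correlation). All 30 genes of the DNA replication and G1/S list fell as well, again also over the list alone, with a median of -2.89 (camera adjusted p = 4.4e-21, adjusted p = 0.268 with an estimated correlation). In the cholesterol synthesis list 12 of 17 genes fell (13 down over the list alone, median -0.85, camera adjusted p = 0.0107, adjusted p = 0.713 with an estimated correlation). INSIG1 was among them (log2 change -1.58 ± 0.43, adjusted p = 0.0184). The 8 largest falls were histone genes, whose near-identical copies make each value uncertain.

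The limma test passed 626 rises and 2235 falls with nutlin, 235 and 798 of them at least 2-fold. Scaling by the median of ratios moved the median change of all genes by 0.206, and the split moved with it. Of the genes past the threshold 21.9% were rises, and 48.1% under median-of-ratios scaling. In all 2861 genes passed, 4382 without the 3 diverging libraries and 4 with close pairs counted once. Leaving out 1 library gave from 1478 (without CTR siRNA replicate 1) to 1807 (without CTR siRNA replicate 2).

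**Figure D3:**
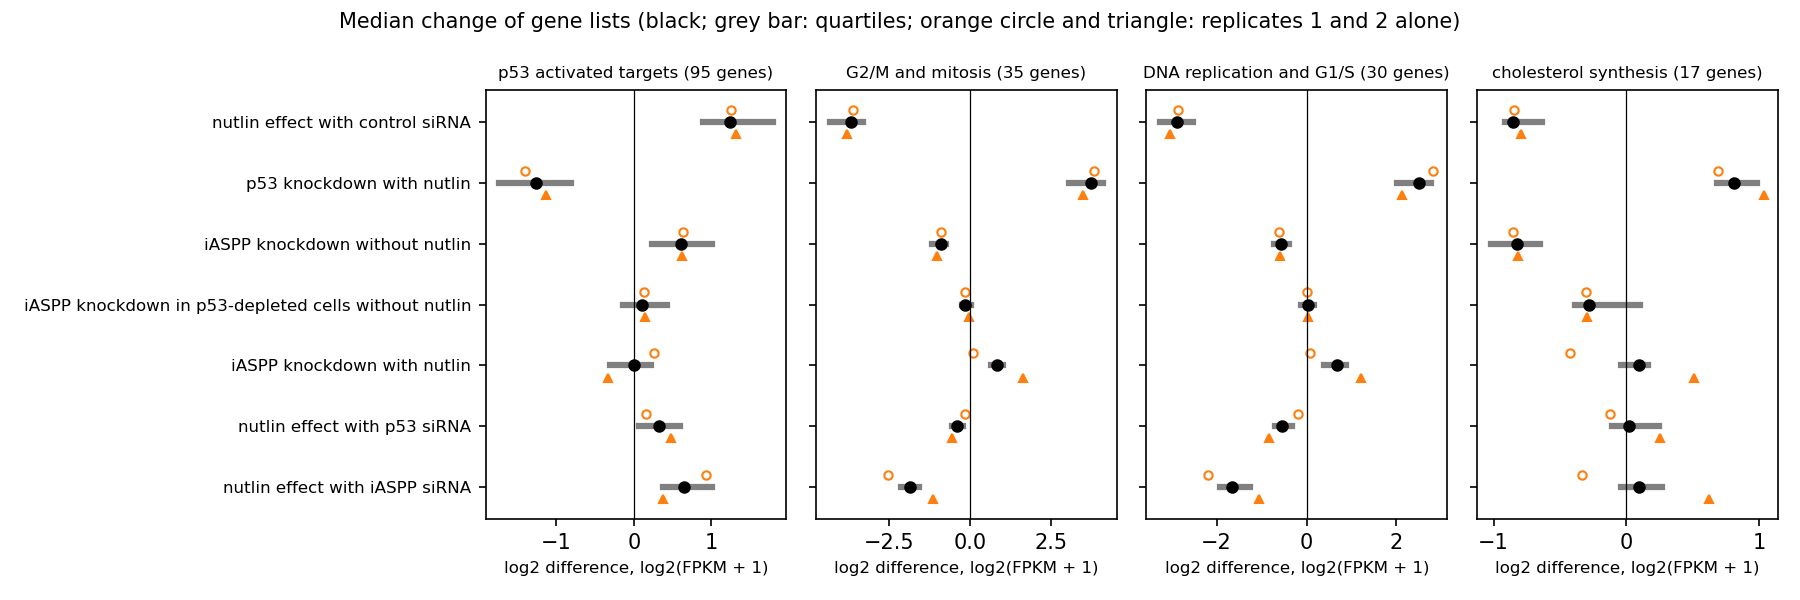
Median log2 difference of 4 fixed gene lists in 7 comparisons, with bars for the quartiles over genes and symbols for each replicate; the p53 activated targets had a median of 1.25 with nutlin and 0.61 with iASPP siRNA alone.

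The next comparison asked how the nutlin-treated state changed when p53 was depleted, p53 siRNA+nutlin against CTR siRNA+nutlin. Both this comparison and the first use the CTR siRNA+nutlin libraries. CDKN1A fell from 1543 ± 47.7 FPKM to 77.2 ± 42.1 FPKM (n = 2, log2 change -4.42 ± 0.38, adjusted p = 4.3e-05). MDM2 fell from 232 ± 10.2 FPKM to 20.3 ± 11.2 FPKM (log2 change -3.56 ± 0.45, adjusted p = 3.4e-04) and TP53I3 from 265 ± 29.9 FPKM to 9.29 ± 4.22 FPKM (log2 change -4.75 ± 0.39, adjusted p = 3.4e-05). Of the 95 p53 activated targets 74 fell and 2 rose (2 up and 81 down over the list alone, median -1.27, camera adjusted p = 1.3e-48, adjusted p = 0.262 with an estimated correlation). AURKB rose to 83.7 ± 18.9 FPKM (log2 change 4.47 ± 0.27, adjusted p = 9.9e-06) and RRM2 to 46.4 ± 10.9 FPKM (log2 change 4.14 ± 0.43, adjusted p = 9.7e-05). In the G2/M list 35 of 35 rose (35 up over the list alone, median 3.74, camera adjusted p = 7.8e-29, adjusted p = 0.268 with an estimated correlation). In the G1/S list 29 of 30 rose (30 up over the list alone, median 2.51, camera adjusted p = 5.3e-20, adjusted p = 0.272 with an estimated correlation). Of the cholesterol synthesis genes 10 of 17 rose, INSIG1 by 1.82 (12 up over the list alone, camera adjusted p = 0.00230, adjusted p = 0.685 with an estimated correlation). In all 1833 genes rose and 564 fell. Of these, 76.5% were rises, and 51.6% under median-of-ratios scaling. The total of 2397 became 3581 without the 3 diverging libraries and 1 with close pairs counted once. With 1 library left out the total ranged from 1096 (without CTR siRNA+nutlin replicate 1) to 2159 (without p53 siRNA+nutlin replicate 2).

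Whether the nutlin effect itself differed with p53 siRNA was tested as an interaction. The nutlin effect was lower with p53 siRNA for TP53I3 (log2 change -4.80 ± 0.55, adjusted p = 0.00134), CD82 (ENSG00000085117, log2 change -3.54 ± 0.48, adjusted p = 0.00241), MDM2 (log2 change -3.14 ± 0.64, adjusted p = 0.0129) and CDKN1A (log2 change -2.24 ± 0.54, adjusted p = 0.0258). It was higher for AURKB (log2 change 4.22 ± 0.38, adjusted p = 5.6e-04) and RRM2 (log2 change 4.09 ± 0.60, adjusted p = 0.00316). Among the p53 activated targets 32 of 95 had a lower nutlin effect (1 up and 54 down over the list alone, median -0.97, camera adjusted p = 1.7e-30, adjusted p = 0.268 with an estimated correlation). For 34 of 35 G2/M genes it was higher (35 up over the list alone, median 3.51, camera adjusted p = 8.1e-28, adjusted p = 0.268 with an estimated correlation). The same held for 29 of 30 G1/S genes (29 up over the list alone, median 2.14, camera adjusted p = 3.9e-19, adjusted p = 0.272 with an estimated correlation). The interaction was above 0 for 816 genes and below 0 for 224. 78.5% were above 0, and 59.2% under scaling. In all 1040 genes passed, 2606 without the 3 diverging libraries and 1 with close pairs counted once. Leaving out 1 library gave from 403 (without p53 siRNA replicate 1) to 984 (without p53 siRNA+nutlin replicate 2).

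In cells with p53 siRNA nutlin still changed some genes. GDF15 rose from 86.4 ± 2.45 FPKM to 363 ± 127 FPKM (n = 2, log2 change 2.01 ± 0.24, adjusted p = 0.00701). BBC3 (ENSG00000105327), which encodes the apoptosis inducer PUMA, rose from 2.59 ± 0.194 FPKM to 10.2 ± 1.35 FPKM (log2 change 1.64 ± 0.19, adjusted p = 0.00701). LDHA (ENSG00000134333), a lactate dehydrogenase gene, fell from 1566 ± 54.1 FPKM to 982 ± 37.9 FPKM (log2 change -0.67 ± 0.069, adjusted p = 0.00701). CDKN1A stood at 15.1 ± 0.775 FPKM without and 77.2 ± 42.1 FPKM with nutlin, libraries 47.4 and 107, and did not pass the threshold (log2 change 2.17 ± 0.38, adjusted p = 0.0502). The p53 activated targets had a median of 0.32, with 2 of 95 past the threshold (11 up over the list alone, camera adjusted p = 5.7e-10, adjusted p = 0.526 with an estimated correlation). Part of this shift went with the diverging library. In p53 siRNA+nutlin 76 of 95 were higher in replicate 2 than in replicate 1, with a median difference of 0.298. The limma test passed 15 rises and 9 falls, and 1607 genes had an unadjusted p under 0.05. The total of 24 became 278 without the 3 diverging libraries and 0 with close pairs counted once. With 1 library left out the total ranged from 0 (without p53 siRNA replicate 1) to 237 (without p53 siRNA+nutlin replicate 1).

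Without nutlin, p53 siRNA against CTR siRNA asked what basal p53 contributed. NCSTN (ENSG00000162736), a gamma-secretase subunit gene, fell from 16.6 ± 0.658 FPKM to 7.84 ± 0.809 FPKM (n = 2, log2 change -0.997 ± 0.12, adjusted p = 0.0297). The oxidoreductase gene NQO1 (ENSG00000181019) fell from 222 ± 0.219 FPKM to 139 ± 15.1 FPKM (log2 change -0.68 ± 0.094, adjusted p = 0.0438). S100A6 (ENSG00000197956), a calcium-binding protein gene, fell from 5499 ± 39.4 FPKM to 3881 ± 27.6 FPKM (log2 change -0.50 ± 0.07, adjusted p = 0.0438). The last fall was RPL17-C18orf32 (-1.46), a readthrough gene that shares sequence with RPL17 and is uncertain for that reason. For NCSTN and NQO1 the p53 by iASPP interaction without nutlin, given below, was opposite in sign to the fall and larger. Neither gene was therefore lower with p53 siRNA in iASPP-depleted cells, and whether their falls come from loss of p53 was not tested. CDKN1A stood at 71.7 ± 1.42 FPKM with CTR siRNA and 15.1 ± 0.775 FPKM with p53 siRNA (log2 change -2.18 ± 0.38, adjusted p = 0.0864), short of the threshold. The p53 activated targets shifted down as a list, median -0.28, although 0 of 95 passed the limma test (0 higher and 27 lower at an unadjusted p under 0.05, 4 down over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.630 with an estimated correlation). The G2/M list had a median of 0.22 with 0 of 35 genes past the limma threshold (1 higher and 0 lower at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p = 0.0140, adjusted p = 0.818 with an estimated correlation). The limma test passed 0 rises and 4 falls, and 1379 genes had an unadjusted p under 0.05. In all 4 genes passed, 841 without the 3 diverging libraries and 1 with close pairs counted once. Leaving out 1 library gave from 0 (without CTR siRNA replicate 1) to 7 (without p53 siRNA replicate 2). With the replicate block 0 genes passed limma, so these calls were lost.

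Depletion of iASPP, an inhibitor of p53 family proteins, was then compared with CTR siRNA without nutlin. BTG2 (ENSG00000159388, GRCh38 chromosome 1 from 203305491 to 203309602, plus strand), an antiproliferative gene, rose from 7.53 ± 0.0545 FPKM to 58.0 ± 1.49 FPKM (n = 2, log2 change 2.79 ± 0.32, adjusted p = 0.00202). CDKN1A rose from 71.7 ± 1.42 FPKM to 409 ± 3.25 FPKM (log2 change 2.49 ± 0.38, adjusted p = 0.00647) and TP53I3 from 7.60 ± 1.19 FPKM to 25.2 ± 4.64 FPKM (log2 change 1.61 ± 0.39, adjusted p = 0.0318). MDM2 stood at 13.3 ± 0.0845 FPKM and 28.8 ± 0.852 FPKM and did not pass (log2 change 1.06 ± 0.45, adjusted p = 0.166). CCND1 (ENSG00000110092, GRCh38 chromosome 11 from 69641087 to 69654474, plus strand), which encodes cyclin D1, rose from 63.4 ± 0.469 FPKM to 245 ± 2.50 FPKM (log2 change 1.93 ± 0.12, adjusted p = 6.5e-05). Of the 95 p53 activated targets 28 rose (46 up and 1 down over the list alone, median 0.61, camera adjusted p = 7.5e-22, adjusted p = 0.272 with an estimated correlation). In growth arrest 8 of 17 rose (9 up over the list alone, camera adjusted p = 1.6e-10, adjusted p = 0.272 with an estimated correlation). In apoptosis 9 of 21 rose, PMAIP1 by 1.26 (15 up over the list alone, camera adjusted p = 1.2e-11, adjusted p = 0.268 with an estimated correlation). In metabolism 7 of 20 rose (13 up over the list alone, camera adjusted p = 1.6e-08, adjusted p = 0.272 with an estimated correlation).

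Falls with iASPP siRNA included NDRG1 (ENSG00000104419, GRCh38 chromosome 8 from 133237171 to 133302022, minus strand), a gene known to respond to low oxygen, from 53.9 ± 1.40 FPKM to 9.18 ± 1.19 FPKM (n = 2, log2 change -2.44 ± 0.36, adjusted p = 0.00597). INSIG1 (ENSG00000186480, GRCh38 chromosome 7 from 155297776 to 155310235, plus strand), a regulator of sterol synthesis, fell from 68.9 ± 4.79 FPKM to 12.6 ± 0.665 FPKM (log2 change -2.36 ± 0.43, adjusted p = 0.0126). In the cholesterol synthesis list 7 of 17 fell (12 down over the list alone, median -0.82, camera adjusted p = 3.4e-05, adjusted p = 0.526 with an estimated correlation). The ATF4 and ER stress list had 3 of 14 falls, ASNS -1.80, PHGDH -1.80 and PSAT1 -0.66, all genes of amino acid synthesis (5 down over the list alone, camera adjusted p = 0.0121, adjusted p = 0.629 with an estimated correlation). Of the G2/M genes 11 of 35 fell, KIF20A at -1.46 (22 down over the list alone, median -0.91, camera adjusted p = 4.2e-10, adjusted p = 0.526 with an estimated correlation). Of the G1/S genes 5 of 30 fell (6 down over the list alone, median -0.58, camera adjusted p = 2.2e-04, adjusted p = 0.694 with an estimated correlation). In all 293 genes rose and 545 fell. Of these, 34.96% were rises, and 45.7% under median-of-ratios scaling. The total of 838 became 2882 without the 3 diverging libraries and 3 with close pairs counted once. With 1 library left out the total ranged from 25 (without iASPP siRNA replicate 1) to 179 (without CTR siRNA replicate 2).

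The same iASPP siRNA was compared in p53-depleted cells, p53+iASPP siRNA against p53 siRNA. PMAIP1 (ENSG00000141682), which encodes the apoptosis inducer NOXA, rose from 32.6 ± 1.94 FPKM to 67.5 ± 0.518 FPKM (n = 2, log2 change 1.03 ± 0.17, adjusted p = 0.0261). The ferritin gene FTH1 (ENSG00000167996) rose from 5656 ± 30.1 FPKM to 7940.5 ± 50.1 FPKM (log2 change 0.49 ± 0.062, adjusted p = 0.00785). IGFL4 (ENSG00000204869), the largest rise, was listed at 0 in both p53 siRNA libraries and at 4.19 and 4.89 FPKM with both siRNAs. CDKN1A stood at 15.1 ± 0.775 FPKM with p53 siRNA and 39.1 ± 1.72 FPKM with both (log2 change 1.32 ± 0.38, adjusted p = 0.127). Of the p53 activated targets 3 of 95 rose, PMAIP1, EPHA2 (0.87) and PLK2 (0.57), with a median of 0.11 (4 up over the list alone, camera adjusted p = 0.00839, adjusted p = 0.798 with an estimated correlation). The apoptosis list had 1 of 21 past the threshold (4 up over the list alone, median 0.31, camera adjusted p = 3.5e-04, adjusted p = 0.417 with an estimated correlation). The reference genes rose in 2 of 12, ACTB by 0.81 (4 up over the list alone, median 0.074, camera adjusted p = 0.0255, adjusted p = 0.272 with an estimated correlation). The limma test passed 56 rises and 45 falls. In all 101 genes passed, 1274 without the 3 diverging libraries and 0 with close pairs counted once. Leaving out 1 library gave from 0 (without p53 siRNA replicate 1) to 32 (without p53 siRNA replicate 2).

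Whether the iASPP effect differed with p53 depleted was tested as an interaction, averaged over both nutlin states. CCND1 alone passed, with a smaller iASPP effect in p53-depleted cells (log2 change -1.06 ± 0.12, adjusted p = 0.0320, adjusted p = 0.164 under scaling). Without nutlin it stood at 70.3 ± 2.25 FPKM with p53 siRNA and 96.7 ± 0.707 FPKM with both (n = 2). The p53 activated targets had a median of -0.21 with 0 of 95 past the limma threshold (2 higher and 8 lower at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p = 7.0e-04, adjusted p = 0.721 with an estimated correlation). Of all genes tested, 1064 genes had an unadjusted p under 0.05. The total of 1 became 906 without the 3 diverging libraries and 2 with close pairs counted once. With 1 library left out the total ranged from 0 (without CTR siRNA replicate 1) to 308 (without iASPP siRNA+nutlin replicate 2). With close pairs counted once the 2 genes were above 0 and the CCND1 call was lost (adjusted p = 1.000), as it was with the replicate block (0 genes by limma). Split by nutlin state, a choice made after the data were examined, the interaction without nutlin passed CCND1 below 0 (log2 change -1.48 ± 0.17, adjusted p = 0.0183) and NQO1 (log2 change 1.17 ± 0.13, adjusted p = 0.0183) and NCSTN (log2 change 1.31 ± 0.16, adjusted p = 0.0206) above it. None of these passed under scaling, where the adjusted p was 0.0728, 0.0728 and 0.0663. Of the total of 3, 3 were among 1248 without the 3 diverging libraries, and 1 gene, none of them, passed with close pairs counted once. The p53 activated targets then had a median of -0.49 with 0 of 95 genes past the limma threshold (2 higher and 25 lower at an unadjusted p under 0.05, 1 up and 9 down over the list alone, camera adjusted p = 4.4e-13, adjusted p = 0.364 with an estimated correlation). With nutlin the limma test passed 0 genes, and 774 had an unadjusted p under 0.05. Without the 3 diverging libraries it passed 274, and with close pairs counted once 1.

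Depletion of p53 on top of iASPP was read from p53+iASPP siRNA against iASPP siRNA without nutlin. p53 siRNA alone also shifted the p53 activated targets down, so falls here do not by themselves show that the rises with iASPP siRNA needed p53. The interaction above compares the iASPP effects directly. PPP1R13L was also less depleted with both siRNAs (14.8% of control) than with iASPP siRNA alone (4.40%). CDKN1A fell from 409 ± 3.25 FPKM to 39.1 ± 1.72 FPKM (n = 2, log2 change -3.35 ± 0.38, adjusted p = 0.00291), and BTG2 from 58.0 ± 1.49 FPKM to 7.55 ± 1.18 FPKM (log2 change -2.79 ± 0.32, adjusted p = 0.00291). Of the 95 p53 activated targets 21 fell and 1 rose (1 up and 49 down over the list alone, median -0.67, camera adjusted p = 4.7e-38, adjusted p = 0.0580 with an estimated correlation). The limma test passed 45 rises and 59 falls, and 29 and 64 under scaling. The total of 104 became 1691 without the 3 diverging libraries and 3 with close pairs counted once.

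With nutlin, iASPP siRNA+nutlin was compared with CTR siRNA+nutlin. CDKN3 (ENSG00000100526), a cell-cycle phosphatase gene, rose from 5.31 ± 0.583 FPKM to 15.1 ± 1.89 FPKM (n = 2, log2 change 1.35 ± 0.17, adjusted p = 0.0123). AURKB rose from 2.89 ± 1.31 FPKM to 14.1 ± 5.83 FPKM (log2 change 1.94 ± 0.27, adjusted p = 0.0123). AREG (ENSG00000109321), which encodes the EGFR ligand amphiregulin, fell from 984 ± 59.8 FPKM to 431 ± 57.3 FPKM (log2 change -1.19 ± 0.14, adjusted p = 0.00914), and NDRG1 from 62.0 ± 2.00 FPKM to 17.6 ± 5.32 FPKM (log2 change -1.79 ± 0.36, adjusted p = 0.0497). Of the p53 activated targets 0 of 95 passed the limma threshold (6 higher and 11 lower at an unadjusted p under 0.05, 1 up and 2 down over the list alone). Their median was 0.0015 and their mean -0.037, so that the median and the direction of the list test, down, differ in sign (camera adjusted p = 0.0288, adjusted p = 0.824 with an estimated correlation). CDKN1A stood at 1543 ± 47.7 FPKM and 1216 ± 622 FPKM, with the iASPP libraries at 1656 and 776 (log2 change -0.44 ± 0.38, adjusted p = 0.612), and MDM2 at 232 ± 10.2 FPKM and 136 ± 20.6 FPKM (log2 change -0.78 ± 0.45, adjusted p = 0.433). The median of the p53 activated targets was 0.26 in replicate 1 and -0.33 in replicate 2. It was 0.23 without the 3 diverging libraries with 23 rises and 5 falls. In the G2/M list 3 of 35 rose (13 up over the list alone, median 0.84, 0.082 in replicate 1 and 1.63 in replicate 2, camera adjusted p = 9.0e-11, adjusted p = 0.526 with an estimated correlation). In the G1/S list 1 of 30 rose (10 up over the list alone, camera adjusted p = 2.5e-08, adjusted p = 0.526 with an estimated correlation). In all 54 genes rose and 28 fell. Of these, 65.9% were rises, and 32.1% under median-of-ratios scaling. With the replicate block 34 genes passed limma, 21 rises and 13 falls. In all 82 genes passed, 1657 without the 3 diverging libraries and 0 with close pairs counted once. Leaving out 1 library gave from 0 (without CTR siRNA+nutlin replicate 1) to 581 (without iASPP siRNA+nutlin replicate 2).

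Nutlin in iASPP-depleted cells, iASPP siRNA+nutlin against iASPP siRNA, raised TP53I3 from 25.2 ± 4.64 FPKM to 194 ± 109 FPKM (n = 2, log2 change 2.78 ± 0.39, adjusted p = 0.00972) and MDM2 from 28.8 ± 0.852 FPKM to 136 ± 20.6 FPKM (log2 change 2.19 ± 0.45, adjusted p = 0.0227). It lowered RRM2 from 40.7 ± 0.296 FPKM to 6.56 ± 6.12 FPKM (log2 change -2.75 ± 0.43, adjusted p = 0.0104). These standard errors come from the spread shared by all groups and are likely too small for the diverging iASPP siRNA+nutlin pair. CDKN1A stood at 409 ± 3.25 FPKM and 1216 ± 622 FPKM (log2 change 1.47 ± 0.38, adjusted p = 0.0501). Of the 95 p53 activated targets 17 rose (48 up over the list alone, median 0.65, camera adjusted p = 1.3e-24, adjusted p = 0.268 with an estimated correlation). Of the G2/M genes 30 of 35 fell (35 down over the list alone, median -1.85, camera adjusted p = 5.0e-28, adjusted p = 0.268 with an estimated correlation). Of the G1/S genes 27 of 30 fell (29 down over the list alone, median -1.66, camera adjusted p = 3.5e-24, adjusted p = 0.268 with an estimated correlation). In all 139 genes rose and 416 fell. The total of 555 became 2952 without the 3 diverging libraries and 5 with close pairs counted once. With 1 library left out the total ranged from 0 (without iASPP siRNA replicate 2) to 1992 (without iASPP siRNA+nutlin replicate 2).

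The interaction test asked whether iASPP siRNA changed the nutlin effect itself. The nutlin effect was lower with iASPP siRNA for CDKN1A (log2 change -2.94 ± 0.54, adjusted p = 0.0354), SFN (ENSG00000175793, log2 change -1.69 ± 0.23, adjusted p = 0.0145) and FDXR (ENSG00000161513, log2 change -1.54 ± 0.27, adjusted p = 0.0315). It was higher for AURKB (log2 change 2.91 ± 0.38, adjusted p = 0.0136) and CDKN3 (log2 change 2.47 ± 0.24, adjusted p = 0.00492). Among the p53 activated targets it was lower for 5 and higher for 1 of 95 (1 up and 29 down over the list alone, median -0.66, camera adjusted p = 6.8e-26, adjusted p = 0.268 with an estimated correlation). That median was -0.33 without iASPP siRNA+nutlin replicate 2. The nutlin effect was higher for 9 of 35 G2/M genes (32 up over the list alone, median 1.81, camera adjusted p = 2.7e-19, adjusted p = 0.353 with an estimated correlation). As given above, the G2/M median of the iASPP effect with nutlin was far higher in replicate 2, a diverging library, than in replicate 1. Part of the G2/M difference therefore went with that library. The interaction was above 0 for 88 genes and below 0 for 21. 80.7% were above 0, and 50% under scaling, with 50 on either side. In all 109 genes passed, 908 without the 3 diverging libraries and 1 with close pairs counted once. Leaving out 1 library gave from 0 (without CTR siRNA replicate 1) to 1230 (without iASPP siRNA+nutlin replicate 1).

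In p53-depleted cells with nutlin, p53+iASPP siRNA+nutlin against p53 siRNA+nutlin, PPP1R13L was the only gene past the limma threshold, and 495 genes had an unadjusted p under 0.05. CDKN1A stood at 77.2 ± 42.1 FPKM and 112 ± 41.1 FPKM, and BTG2 at 9.26 ± 4.38 FPKM and 15.1 ± 1.03 FPKM (n = 2). The p53 activated targets had a median of 0.061 with 0 of 95 past the limma threshold (6 higher and 1 lower at an unadjusted p under 0.05, 0 over the list alone). That median was -0.085 without p53 siRNA+nutlin replicate 1 and -0.15 without p53+iASPP siRNA+nutlin replicate 2. It stayed above 0 with either of the other libraries of this comparison left out. The total of 1 became 318 without the 3 diverging libraries and 1 with close pairs counted once. With 1 library left out the total ranged from 0 (without p53 siRNA+nutlin replicate 1) to 16 (without p53+iASPP siRNA+nutlin replicate 2). With close pairs counted once the gene that passed was a rise, and the PPP1R13L call was lost (adjusted p = 1.00).

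Shared calls were counted for pairs of comparisons that have no library in common. The expected counts take calls as independent, but all comparisons used the same spread of a gene, so they may be too low. Nutlin with CTR siRNA and nutlin with iASPP siRNA shared 93 rises (8.16 expected from independent calls), among them TP53I3, MDM2 and CD82. They also shared 382 falls (87.2), among them RRM2 and CDC6. Of the genes that rose with nutlin 44 fell when p53 was depleted on top of iASPP (3.46 expected), CDKN1A and BTG2 among them. iASPP siRNA without and with nutlin shared 14 rises (1.48) and 12 falls (1.43), the falls including PPP1R13L and NDRG1. iASPP siRNA with p53 present and depleted shared 16 rises (1.54) and 18 falls (2.30). Nutlin and iASPP siRNA, both against CTR siRNA, shared 121 rises (17.2) and 348 falls (114), BTG2 and CDKN1A among the rises. These have their control libraries in common, so part of the excess may come from the shared controls. Simulation with shared controls, in 100 draws, gave a mean correlation of 0.50 (range 0.45 to 0.56), and the correlation here was 0.53. A value near 0.50 is built into groups without effects that share a control, so this does not tell where the 0.53 comes from. The simulated covariance was 0.0379 against 0.192 here, a difference of 0.154. Shared controls alone, at the simulated spread, thus gave less covariance than was found. The simulated groups held no effects, and no draw had more than 0 shared rises or 0 shared falls by limma. Without effects few genes can pass in either comparison, so these simulated counts do not tell how many shared calls come from the common controls. In the order above the totals were 475, 73, 26, 34 and 469 calls, where the 73 are calls in opposite directions. They became 2020, 1330, 761, 559 and 1798 without the 3 diverging libraries and 1, 0, 0, 0 and 1 with close pairs counted once by limma. Leaving out each library in turn gave 0 to 1352, 5 to 32, 0 to 232, 0 to 12 and 12 to 263 in the same order.

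Of the remaining lists, epithelial genes rose with nutlin in 7 of 18 and fell in 1, KRT19 by 1.25 and KRT8 by 0.75 (7 up and 2 down over the list alone, median 0.092, camera adjusted p = 6.1e-04, adjusted p = 0.268 with an estimated correlation). For p53 siRNA+nutlin their median was 0.081, their mean -0.034 and the list test down, with 2 rises and 3 falls (camera adjusted p = 0.0342, adjusted p = 0.417 with an estimated correlation). For the nutlin by p53 interaction the median was 0.033, the mean -0.06 and the list test down (camera adjusted p = 0.0288, adjusted p = 0.417 with an estimated correlation), so that in both cases the median differs in sign from the mean and the test. In the NRF2 list 3 of 17 rose and 1 fell with nutlin, FTH1 by 0.64 (3 up and 1 down over the list alone, camera adjusted p = 0.00899, adjusted p = 0.268 with an estimated correlation). The type I interferon list had a median of -0.11 with nutlin, ISG15 rising by 1.67 and OAS3 changing by -2.03 (1 rise and 2 falls of 15, 1 up and 2 down over the list alone, camera adjusted p = 0.812). NF-kB targets had 1 fall of 12 with nutlin and, with iASPP siRNA, BIRC3 rose by 1.27 (1 down and 1 up over the list alone, camera adjusted p = 0.163 and 0.656). The p53 pathway regulators had 2 rises and 1 fall of 11 with nutlin, MDM2 among the rises (2 up and 1 down over the list alone, camera adjusted p = 0.496). Reference genes fell with nutlin in 8 of 12, HPRT1 at -1.38 and B2M at -0.94 (8 down over the list alone, median -0.44, camera adjusted p = 0.0806). Of 13 marker genes of other cell types only ACTA2, at 0.346 to 58.9 FPKM, passed the level filter, with PTPRC at most 0.243 FPKM, HBB at most 9.65 and CD79A at most 2.25 in any library. None of the 13 mitochondrially encoded genes is in the table.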

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

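All tests of explanations in this section were chosen after the result was seen. The test of the difference itself, an interaction, passed for 1040 genes for nutlin by p53, 109 for nutlin by iASPP and 1 for p53 by iASPP, and the named ones follow with the log2 difference between the effects.

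The nutlin effect was lower with p53 siRNA than with CTR siRNA for LCE1F (-5.72), TP53I3 (-4.80), LCE1C (-4.17), CD82 (-3.54), LCN15 (-3.47), MDM2 (-3.14), CEACAM1 (-2.90), ZNF219 (-2.33), SFN (-2.26), CDKN1A (-2.24), CES2 (-1.93), FDXR (-1.75), ISG15 (-1.67), CDIP1 (-1.57), KRT19 (-1.48), ZMAT3 (-1.39), GDF15 (-1.38), CMBL (-1.33), PLK3 (-1.25), KRT8 (-1.16), TNFRSF10B (-1.07), ASCC3 (-1.05), TKT (-0.94), KRT18 (-0.67). It was higher with p53 siRNA for HIST1H2BO (5.70), HIST1H4A (5.41), SYCE3 (5.25), HMGB2 (4.99), UBE2C (4.89), HIST1H2AH (4.61), HIST1H2AB (4.49), CDK1 (4.39), PLK1 (4.24), AURKB (4.22), RRM2 (4.09), GINS2 (3.25), CDC6 (3.20), FEN1 (3.18), OAS3 (1.61), B2M (1.51), HPRT1 (1.14), PGK1 (0.79), SOD2 (0.71), NQO1 (0.56), PPIA (0.52). The list medians that differed in this way were p53 targets in growth arrest (-1.01), p53 targets in apoptosis (-0.74), p53 targets in metabolism (-1.10), p53 activated targets (-0.97), G2/M and mitosis (3.51), DNA replication and G1/S (2.14), epithelial junctions and keratins (0.033), cholesterol synthesis (0.85), reference genes (0.36). With an estimated correlation none of these list tests passed (lowest adjusted p = 0.268), and the epithelial list, whose test pointed down, had a median of -0.19 under scaling. LCE1 and histone genes have near-identical copies and are uncertain, and SYCE3, LCE1F and LCN15 were listed at 0 in some of the groups.

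With iASPP siRNA the nutlin effect was lower for CDKN1A (-2.94), SFN (-1.69), GALNT5 (-1.64), FDXR (-1.54), ST6GALNAC4 (-1.39), PHPT1 (-1.33), VPS28 (-1.29), RFNG (-1.29), TRIAP1 (-1.11), PLK2 (-1.09), GPX1 (-1.02). It was higher for HIST1H2AB (4.27), EFCAB11 (3.05), AURKB (2.91), NUSAP1 (2.68), RACGAP1 (2.66), DLGAP5 (2.48), CDKN3 (2.47), KIF2C (2.43), NUF2 (2.29), CDC45 (1.997), OAS3 (1.61), RRM1 (1.26), TYMS (0.94), B2M (0.94), NQO1 (0.69). The list medians here were p53 targets in growth arrest (-0.88), p53 targets in apoptosis (-0.85), p53 targets in metabolism (-0.63), p53 activated targets (-0.66), G2/M and mitosis (1.81), DNA replication and G1/S (1.23), cholesterol synthesis (0.91). None of these list tests passed with an estimated correlation (lowest adjusted p = 0.268). Without iASPP siRNA+nutlin replicate 2, a diverging library, the median of the p53 activated targets was -0.335. The higher nutlin effect on the G2/M genes also went in part with that library.

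The iASPP effect was smaller in p53-depleted cells for CCND1 (-1.06). The list medians of this interaction were p53 targets in growth arrest (-0.25), p53 targets in apoptosis (-0.22), p53 activated targets (-0.21), ATF4 and ER stress (0.50), reference genes (0.16). With a correlation estimated from the data no list test of it passed (lowest adjusted p = 0.268).

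In the nutlin groups with p53, iASPP or both siRNAs, replicate 2 stood apart from replicate 1. Deeper sequencing was argued against, because the lowest extra spread of these pairs was 17.44% and the highest of the 5 others, whose replicate 2 was also deeper, was 4.144%. RNA of p53-depleted nutlin-treated cells mixed into the iASPP library was argued against by a share of 0.525 (quartiles 0.334 to 0.664) from p53 activated targets and 0.128 (0.108 to 0.168) from G2/M genes, ranges that a single share would bring together, and in 6 of 7 possible partner groups the ranges were apart. Less complete iASPP depletion as the whole cause was argued against by the p53 activated targets in that library against CTR siRNA+nutlin. Their median of -0.285 (quartiles over genes -0.612 to -0.0028) lay on the other side of 0 from replicate 1 (0.23). This rests on 1 library, whose PPP1R13L level was above that of replicate 1, so weaker depletion as part of the cause stayed open. Less complete p53 depletion in both libraries with p53 siRNA stayed open. p53 activated targets were higher in replicate 2 by medians of at least 0.298 (quartiles 0.0104 to 0.604). G2/M genes with p53 siRNA had a median of -0.415 (quartiles -0.639 to -0.307), with 1 of 35 higher. With both siRNAs, however, their median was -0.0971 with quartiles on both sides of 0 (-0.262 to 0.105) and 12 of 35 higher. Batch, timing and handling were not tested.

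With iASPP siRNA 28 of 95 p53 activated targets rose without nutlin (median 0.61, camera adjusted p = 7.5e-22, adjusted p = 0.272 with an estimated correlation), and with nutlin none passed (median 0.0015). Whether the diverging iASPP library caused that none passed was left open, because in the limma test 8 rose and 0 fell without it, while 0 rose and 10 fell without replicate 1 instead (with all libraries 6 higher and 11 lower at an unadjusted p under 0.05). For the smaller size of the effect that library as the whole cause was argued against, because without it the difference between the nutlin states had a median of -0.335 (quartiles -0.743 to -0.0334), against -0.66 with it, so part of that difference went with the library. An effect of the iASPP siRNA that does not need p53 was left open, since the median of -0.486 (quartiles -0.901 to -0.15) for p53-depleted minus p53-present cells may also follow from weaker iASPP depletion, with PPP1R13L at 14.8% of control with both siRNAs and 4.40% with iASPP siRNA alone. A ceiling of the p53 response under nutlin, and off-target effects of 1 siRNA, were not tested and remain open.

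The small spread of 5 replicate pairs may come from the same libraries sequenced again or from replicate cultures handled alike. Their highest extra spread was 4.144%, against -0.6521% for counting error alone and 17.44% for the lowest of the other pairs, so these cannot be told apart with these values.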

How the results depend on the processing

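The counts, named genes and list medians of the 12 planned comparisons were redone under the alternatives, and the cause of a change was not tested unless stated. With a pseudocount of 0.1, p53 knockdown without nutlin passed 7 genes and iASPP knockdown in p53-depleted cells with nutlin 0. The median of the p53 activated targets for iASPP knockdown with nutlin changed sign to -0.00070. With no filter beyond a mean above 0, iASPP knockdown in p53-depleted cells with nutlin passed 0 genes, nutlin with iASPP siRNA 306, the nutlin by iASPP interaction 65 and the p53 by iASPP interaction 0. The shared calls were 47 for nutlin against p53 depletion on top of iASPP, 12 for iASPP siRNA without and with nutlin and 256 for nutlin with CTR and with iASPP siRNA, and the same list median became -0.0075. Under median-of-ratios scaling the p53 by iASPP interaction passed 0 genes. The median of p53 activated targets for iASPP knockdown with nutlin was -0.088, and the epithelial list changed sign for p53 knockdown with nutlin (-0.14) and for the nutlin by p53 interaction (-0.19). With a replicate block, p53 knockdown without nutlin passed 0 genes, iASPP knockdown with nutlin 34, iASPP knockdown in p53-depleted cells with nutlin 0 and the p53 by iASPP interaction 0, and iASPP siRNA without and with nutlin shared 13 calls. The replicate block changed no other count by more than 1.5 times. Over 28 pairs of groups the differences between replicates had correlations of -0.032 to 0.30 with a median of 0.023, and 3 pairs lay over 0.1. On the second principal component the 3 diverging libraries all lay above their replicate 1, at 23.9 against 6.98 with p53 siRNA, 8.21 against -22.8 with iASPP siRNA and 12.4 against -13.3 with both. Of 467 named gene values, scaling left 424 the same, weakened 37 and strengthened 6, close pairs counted once weakened 327, and none was reversed in any setting.

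The 3 diverging libraries enter the spread estimate of every comparison, and without them the counts grew: nutlin 4382, p53 knockdown 841, iASPP knockdown 2882 and, in p53-depleted cells, 1274. With nutlin, iASPP knockdown passed 1657 genes and 318 in p53-depleted cells, nutlin passed 278 with p53 siRNA and 2952 with iASPP siRNA, and the interactions 2606 for nutlin by p53, 908 for nutlin by iASPP and 906 for p53 by iASPP. The shared calls were 1330, 761, 559, 2020, 1798 in the order of the report from p53 depletion on top of iASPP, iASPP siRNA with nutlin, iASPP siRNA with p53 depleted, nutlin with iASPP siRNA and the pair with shared controls. List medians changed sign for p53 targets in metabolism (0.23) and cholesterol synthesis (-0.41) for iASPP knockdown with nutlin, G2/M for the p53 by iASPP interaction (0.21), G1/S for iASPP knockdown in p53-depleted cells with nutlin (-0.15) and cholesterol synthesis for nutlin with iASPP siRNA (-0.33). Without the 3 libraries the spread was estimated from the 5 close pairs alone. Those pairs may be the same libraries sequenced again, so the larger counts may rest on technical spread.

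With close pairs counted once, which left 11 samples and 3 residual degrees of freedom, most calls were lost: nutlin 4, p53 knockdown 1, iASPP knockdown 3 and 0 in p53-depleted cells, p53 knockdown with nutlin 1, iASPP knockdown with nutlin 0, nutlin with p53 siRNA 0 and with iASPP siRNA 5. The interactions passed 1 gene for nutlin by p53, 1 for nutlin by iASPP and 2 for p53 by iASPP, and the shared calls were 0, 0, 0, 1, 1 in the same order. Of the list tests 79 passed with close pairs counted once at the preset correlation. With an estimated correlation 0 passed (lowest adjusted p = 0.262), and 0 with close pairs counted once as well (lowest adjusted p = 0.751). With close pairs counted once all 3 residual degrees of freedom came from the 3 diverging pairs, which had the larger spread. The loss of gene calls is therefore in part built into that setting. Split by nutlin state, the p53 by iASPP interaction passed 3 genes without nutlin and 0 with it. For these splits and the histone and hypoxia lists no values with the other pseudocount, filter or block were compared, and for p53 depletion on top of iASPP only the shared calls were.

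Leaving out each library in turn takes 1 residual degree of freedom, and the library left alone in its group is assumed to vary like the other groups. The counts then ranged as follows: nutlin 1478 to 1807, p53 knockdown 0 to 7, iASPP knockdown 25 to 179, iASPP knockdown in p53-depleted cells 0 to 32, p53 knockdown with nutlin 1096 to 2159, iASPP knockdown with nutlin 0 to 581, the same in p53-depleted cells 0 to 16, nutlin with p53 siRNA 0 to 237, nutlin with iASPP siRNA 0 to 1992, nutlin by p53 403 to 984, nutlin by iASPP 0 to 1230, p53 by iASPP 0 to 308. The libraries at either end are named in the report. List tests that passed ranged over 77 to 93, and the shared calls over 5 to 32, 0 to 232, 0 to 12, 0 to 1352, 12 to 263 in the order above. The list medians that changed sign when 1 library was left out had these ranges. For iASPP knockdown with nutlin they were -0.29 (without iASPP siRNA+nutlin replicate 1) to 0.23 (without iASPP siRNA+nutlin replicate 2) for p53 activated targets, -0.26 (without iASPP siRNA+nutlin replicate 1) to 0.40 (without iASPP siRNA+nutlin replicate 2) for growth arrest, -0.25 (without iASPP siRNA+nutlin replicate 1) to 0.42 (without iASPP siRNA+nutlin replicate 2) for apoptosis, -0.39 (without iASPP siRNA+nutlin replicate 1) to 0.23 (without iASPP siRNA+nutlin replicate 2) for metabolism and -0.41 (without iASPP siRNA+nutlin replicate 2) to 0.52 (without iASPP siRNA+nutlin replicate 1) for cholesterol synthesis. For iASPP knockdown in p53-depleted cells with nutlin they were -0.059 (without p53+iASPP siRNA+nutlin replicate 2) to 0.32 (without p53 siRNA+nutlin replicate 2) for apoptosis, -0.15 (without p53+iASPP siRNA+nutlin replicate 2) to 0.25 (without p53+iASPP siRNA+nutlin replicate 1) for p53 activated targets and -0.20 (without p53 siRNA+nutlin replicate 2) to 0.44 (without p53 siRNA+nutlin replicate 1) for G1/S. The epithelial list in the nutlin by p53 interaction ranged over -0.036 (without CTR siRNA replicate 2) to 0.088 (without p53 siRNA+nutlin replicate 1). In the p53 by iASPP interaction G1/S ranged over -0.23 (without iASPP siRNA+nutlin replicate 1) to 0.27 (without iASPP siRNA+nutlin replicate 2) and G2/M over -0.31 (without iASPP siRNA+nutlin replicate 1) to 0.28 (without iASPP siRNA+nutlin replicate 2). A count model was not run because no counts were used here, and with 2 libraries per group the smallest exact p is 0.333.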

Other observations

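Histone genes were taken by HIST symbol, and whether each is transcribed with DNA replication was not checked. Of 70 such genes 47 were measured. With nutlin 36 fell and 1 rose, with a median of -3.41 (limma camera p = 3.8e-12, p = 0.0857 with an estimated correlation). HIST1H3B went from 588 ± 17.4 FPKM to 11.4 ± 7.96 FPKM (n = 2) and HIST1H2BM from 203 ± 41.0 FPKM to 2.41 ± 3.41 FPKM. In p53 siRNA+nutlin against CTR siRNA+nutlin 31 rose, with a median of 2.37 (limma camera p = 1.3e-08, p = 0.147 with an estimated correlation). With p53 siRNA nutlin gave a median of -1.88, with 0 genes past the limma threshold and 30 lower at an unadjusted p under 0.05, and 25 down when adjusted over the list alone (limma camera p = 2.9e-20, p = 0.0314 with an estimated correlation, p = 0.0859 with close pairs counted once as well). That median was -0.97 in replicate 1, -2.72 in replicate 2 and -1.02 without the 3 diverging libraries, where 8 fell. With iASPP siRNA nutlin lowered 18 of them, with a median of -1.99 (limma camera p = 5.6e-13, p = 0.0763 with an estimated correlation). The list was chosen after the data were seen, these genes have near-identical copies, and their transcripts mostly lack the poly(A) tail on which the mRNA purification relies, so the values are uncertain.

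Of 36 listed hypoxia-inducible genes 32 were measured. With iASPP siRNA without nutlin 8 fell (14 over the list alone), with a median of -0.48, -0.38 under scaling (limma camera p = 8.2e-07, p = 0.0170 with an estimated correlation, p = 0.0700 with close pairs counted once as well). PLOD2, a collagen lysyl hydroxylase gene, fell from 11.6 ± 1.07 FPKM to 2.28 ± 0.0172 FPKM (n = 2, log2 change -1.94 ± 0.32, adjusted p = 0.00914), and ALDOC, a glycolytic aldolase gene, from 90.2 ± 4.26 FPKM to 22.1 ± 0.755 FPKM (log2 change -1.98 ± 0.42, adjusted p = 0.0205). ENO2, an enolase gene, stood at 21.3 ± 1.60 FPKM and 9.71 ± 1.10 FPKM. In p53-depleted cells 1 fell with iASPP siRNA, and the median was -0.087 (limma camera p = 0.0788, p = 0.316 with an estimated correlation). The interaction without nutlin had a median of 0.50, 0.42 under scaling, with 0 genes past the limma threshold and 9 higher at an unadjusted p under 0.05 (limma camera p = 3.8e-04, p = 0.0624 with an estimated correlation), and 4 up when adjusted over the list alone. It passed 11 genes without the 3 diverging libraries. In p53+iASPP siRNA against iASPP siRNA 1 rose (8 over the list alone), with a median of 0.26, 0.17 under scaling (limma camera p = 8.3e-04, p = 0.0762 with an estimated correlation, p = 0.187 with close pairs counted once as well). With nutlin the medians of the iASPP effect were -0.068 with p53 present (-0.17 in replicate 1, -0.069 in replicate 2 and -0.16 under scaling) and -0.31 with p53 depleted (-0.47, -0.099 and -0.28). Their tests gave limma camera p = 0.00104, p = 0.0809 with an estimated correlation, and camera p = 1.2e-04, p = 0.0469 with an estimated correlation, in that order, and with close pairs counted once as well p = 0.157 and 0.114. Without the 3 diverging libraries the medians were -0.16 and -0.47. Nutlin alone had 1 rise and 11 falls, with a median of -0.47, -0.25 under scaling (limma camera p = 0.0222, p = 0.201 with an estimated correlation). This list too was chosen after the data were seen, and its p-values are unadjusted. Oxygen, cell density and medium were not analysed here.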
